A study of Mus musculus with 2 samples.

How the data were processed

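The study measured polyA RNA of single mammary gland cells with the 10x Genomics 3' gene expression kit (V3 chemistry), per the labels' protocols, in 2 libraries, 1 labelled WT and 1 labelled Fgd5-ko. The title of the library labelled Fgd5-ko has the word cko, a usual short form of conditional knockout. The cell types in which Fgd5 was deleted, its deleted part and the word P4 in both titles are not explained in the sources used here. The authors deposited, for each library, UMI counts per gene and barcode with no normalization, made with a Cell Ranger program whose version is 3.1.0 per the file headers. The submitters' processing notes name Cell Ranger, Seurat 3.0 and the mm9 build; which step used which, and the annotation, are not given in the sources used here. UMI counting removes amplification copies, but 3' tags do not show which exons a molecule held. The authors also deposited 1 table of cell barcodes with t-SNE coordinates, which have no unit and were not used as measurements.

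Cells were those of the authors' table, which tells the libraries apart by a barcode suffix. All 6588 barcodes with suffix 1 occur in the library labelled WT and all 6064 with suffix 2 in the library labelled Fgd5-ko, whereas 21 and 27 occur in the other library. The authors' filter is not given in the sources used here. Listed cells had 1563 to 15288 UMIs in the library labelled WT and 3634 to 40227 in the library labelled Fgd5-ko, and at most 19.95% and 19.9% mitochondrially encoded UMIs. Of the barcodes outside the table, those with at least 1000 UMIs, 500 genes and at most 15% mitochondrially encoded UMIs (3490 and 1626) were clustered separately and serve as background and for comparison. Their classes were made up of clusters in unlike proportions in the 2 libraries, so ratios within these classes mix composition with expression. Scrublet, as run by scanpy for each library with an expected rate of 8%, called 28 cells (0.425%) and 0 cells as doublets. That is too few to be a working call, so doublets remain in the data, and cells with UMIs of other cell types may include them.

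Counts were scaled to 10000 per cell and log-transformed. On 2000 highly variable genes and 30 principal components, cells of both libraries were clustered together with the Leiden algorithm (15 neighbours, resolution 1) with no batch correction. A cluster was called X-like from 12 lists of cell type markers (basal, luminal progenitor and alveolar, hormone-sensing luminal, endothelial, fibroblast, pericyte and vascular smooth muscle, T and NK, B cell, myeloid, adipocyte, Schwann and erythroid). It took the name of its highest list where that list's score led the next by a log2 margin of at least 1, at least 3 of that list's markers were found in at least 10% of its cells and its top 10 genes did not hold more markers of another class. The scoring rule and these limits were set after the data were seen; the markers were not. Basal-like cells were clustered again at resolution 0.5. The computations used Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3, scanpy 1.11.5, scikit-learn 1.9.0, leidenalg 0.10.2, igraph 0.11.9 and matplotlib 3.10.9.

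UMIs of the basal-like class were summed per library and divided by the class total to give CPM, and the log2 ratio is the library labelled Fgd5-ko over the library labelled WT. With 1 library per group there was no test. CPM have exact Poisson intervals, shares have Clopper-Pearson intervals and ratios have exact conditional intervals, all at 95% and for counting error only. A count of 0 allows up to 3 counts. The genes named are Fgd5, then the 12 highest and 12 lowest log2 ratios among genes with a mean CPM of at least 50, leaving out mitochondrially encoded and ribosomal protein genes, haemoglobins and genes of the sex chromosomes named in the rule. Named too are the 2 to 4 members of each list with the largest absolute ratio at a mean CPM of at least 20, and Procr. Dcn, Cdh5, Col1a1, Col3a1, Pdgfra and the genes that lead clusters were named after their values were seen. Ribosomal pseudogenes with Gm names cannot be told by symbol and were not left out. Of the list members 2 were found by gene ID because the files use the older symbols Cyr61 and Ctgf.

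Of the 24 gene lists, each member needed at least 20 UMIs over both libraries. A list's excess is its median log2 ratio less the median of 10000 random lists of the same size matched on mean expression, and its percentile is its rank among them, as a description of these libraries. The lists are contractile and basal identity, luminal identity, milk and alveolar, mesenchymal and EMT, basal stem-cell associated, Wnt pathway, Notch pathway, Hippo YAP targets, FGD family and CDC42 signalling, basement membrane, S phase, G2/M phase, immediate early, heat shock, interferon response, NF-kB and inflammation, antigen presentation, unfolded protein response, p53 targets, glycolysis and hypoxia, cholesterol synthesis, mitochondrially encoded, nuclear oxidative phosphorylation and ribosomal proteins. Several genes sit in more than 1 list.

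Shares of cells with a UMI were compared after each cell was thinned at random to 2000 UMIs; 61 basal-like cells of the library labelled WT and 0 of the other were shallower and left out. The draw was changed once after its results were seen, to a separate random stream per cell, because leaving out a few cells had redrawn all others. Over 10 draws the luminal keratin share was 25.3% to 26.4% and 11.2% to 12.6%, the Mki67 or Top2a share 1.54% to 1.86% and 9.56% to 10.04%, the Procr share 0.146% to 0.356% and 0.752% to 0.919%, and the Fgd5 share 0.0648% to 0.162% and 0.635% to 0.936%. The draw reported has the lowest luminal keratin and Fgd5 shares of the library labelled WT among them.

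Gene positions and transcript lengths are from the GENCODE M21 annotation of GRCm38, since the deposited files hold none; 99.6% of the gene IDs are in it. A gene's length is the median of its basic transcripts. This was chosen over the longest transcript after the lengths of a few named genes were seen, and both are given in the closing section. The ratios, intervals, lists and thinning were tested on simulated counts for the basal-like comparison, after a first run on the real files. Intervals held the true value for 95.3% of 14783 unchanged genes, and 50 genes each changed by -2, -1, 1 and 2 on the log2 scale came out at medians of -2.02, -1.00, 0.98 and 1.99. With no list changed, 23 of 24 lay inside the middle 95%.

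Alternatives set before the data were examined were the scaling of the sums (TMM, median ratio), equal weight of cells, thinning before summing, a stricter cell filter (at least 1000 genes, at most 10% mitochondrially encoded UMIs), removal of Scrublet calls, all listed cells, other minimum counts, clustering resolutions, thinning depths and centring of genes within libraries. Added after the data were seen were random lists matched on length, cycling clusters left out, cells of 4000 to 12000 UMIs, cells between the 25th and 75th percentiles of UMIs of their library, unlisted basal-like cells added, centring for the clusters of basal-like cells, other thinning depths for Procr and the longest transcript. The range from the 25th to the 75th percentile was chosen after the range of 4000 to 12000 UMIs had brought the excess of the cell-cycle lists below 0.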

Results

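Gene expression was measured in single cells sorted as CD24high CD29+ from the mouse mammary gland, in C57BL/6 mice. That the cells were basal is read below from their markers and not from the gate. There were 2 libraries, 1 whose genotype label is WT and 1 whose genotype label is Fgd5-ko. The question set by the labels was how basal cells differ when Fgd5, a guanine nucleotide exchange factor for the small GTPase Cdc42, is depleted. The library labelled WT held 10735 barcodes with 60566053 UMIs (unique molecules counted). The library labelled Fgd5-ko held 8798 barcodes with 136697801 UMIs. The authors' table of cells kept 6588 and 6064 of these, with a median of 4954 and 15712 UMIs per cell and 1679 and 3710 detected genes. Mitochondrially encoded genes took a median of 4.87% and 4.63% of UMIs per cell. With 1 library per group there was no measure of the spread between animals, so no difference below has a replicate check. All intervals are exact 95% intervals that cover counting error only.

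Fgd5 went against the label of its library. In basal-like cells it was counted at 23 UMIs (0.664 CPM, 0.421 to 0.996) in the library labelled WT and at 416 UMIs (4.05 CPM, 3.67 to 4.46) in the library labelled Fgd5-ko. The log2 ratio was 2.61 (2.01 to 3.28) in favour of the library labelled Fgd5-ko. Fgd5 was uneven among clusters of basal-like cells. In the library labelled Fgd5-ko a cluster of 952 cells was at 1.39 CPM (0.779 to 2.30) and the others at 2.97 to 6.95 CPM. In the library labelled WT a cluster of 846 cells was at 1.64 CPM (0.817 to 2.93), and the largest, of 4546 cells, at 0.371 CPM. The gene (ENSMUSG00000034037) lies on chromosome 6 from 91978878 to 92076004 on the plus strand of GRCm38. The part that was deleted is not given in the labels, and 3' tags outside it would leave the label unchecked. Every direction below is therefore that of the library labelled Fgd5-ko over the library labelled WT, and not of Fgd5 loss. With every cell thinned to 2000 UMIs, 4 of 6173 cells (0.0648%, 0.0177 to 0.166) and 50 of 5984 cells (0.836%, 0.621 to 1.10) had an Fgd5 UMI. Unthinned, the shares were 0.321% and 6.40%. In fibroblast-like cells, thinned alike, the shares were 0.393% (0.107 to 1.004) and 0.532% (0.110 to 1.55), at median depths of 6590.5 and 12765 UMIs. The CPM of fibroblast-like cells went the other way from these shares, at 4.34 (2.95 to 6.16) and 2.87 (1.80 to 4.34), a log2 ratio of -0.60 (-1.46 to 0.24), so no order between the libraries is read from them. In the library labelled WT Fgd5 was thus lower in basal-like than in fibroblast-like cells, and in the library labelled Fgd5-ko the intervals of the 2 classes overlapped. The endothelial marker Cdh5 was at 13.3 and 0.521 CPM in fibroblast-like cells, so endothelial RNA may add unequally to their Fgd5. The random draw gave the lowest share of the library labelled WT among 10 draws, whose medians in basal-like cells were 0.1215% and 0.735%. The ratio moved with the UMI range of the cells, to 1.26 (0.36 to 2.18) among cells of 4000 to 12000 UMIs.

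Procr, a surface receptor that marks a small population of basal cells with stem-cell activity, was also higher in the library labelled Fgd5-ko. It was counted at 41 UMIs (1.18 CPM, 0.849 to 1.61) against 453 UMIs (4.41 CPM, 4.01 to 4.84), a log2 ratio of 1.90 (1.44 to 2.40). At 2000 UMIs per cell, 0.194% (0.101 to 0.339) of basal-like cells in the library labelled WT and 0.836% (0.621 to 1.10) in the library labelled Fgd5-ko had a Procr UMI, and 0.658% and 5.65% unthinned. Fibroblast-like cells, which carried Procr themselves at 130 and 239.5 CPM, had shares of 20.6% and 27.3%. The fibroblast markers in basal-like cells, taken at the ratio of Procr to each marker in fibroblast-like cells, correspond to amounts of Procr that differ widely. All 8 markers together correspond to 0.893 and 2.24 CPM, and without Dcn to 0.1915 and 0.282 CPM. Single markers ranged in the library labelled WT from Col1a1 (0.1355 CPM) to Dcn (2.75 CPM) and in the library labelled Fgd5-ko from Col3a1 (0.166 CPM) to Dcn (5.13 CPM), with Pdgfra at 1.19 and 1.59 CPM. Dcn itself stood at 161 and 224 CPM in basal-like cells and Col3a1 at 10.6 and 3.75 CPM. Basal-like cells thus did not carry Dcn and Col3a1 in the ratio of fibroblast-like cells, where Dcn was at 7629 and 10466 CPM and Col3a1 at 6857 and 5405 CPM.

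Nearly all listed cells were basal-like. This class, defined by keratins 5 and 14, smooth muscle actin and other markers of contractile basal cells, held 6234 cells of the library labelled WT (94.6%, 94.1 to 95.2) and 5984 of the library labelled Fgd5-ko (98.7%, 98.4 to 98.95). Luminal progenitor and alveolar-like cells were 118 (1.79%) and 17 (0.280%). Hormone-sensing luminal-like cells were 53 (0.804%) and 5 (0.0825%), and T and NK-like cells were 15 (0.228%) and 5 (0.0825%). Clusters with no name held 168 (2.55%) and 53 (0.874%) cells. The sort and the authors' selection of cells both set these shares.

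Within basal-like cells, summed markers of most other cell types stayed low. Myeloid markers were at 15.3 and 3.90 CPM (log2 ratio -1.97), erythroid markers at 0.664 and 0.214 CPM (-1.63) and endothelial markers at 18.3 and 11.8 CPM (-0.63). Pericyte and vascular smooth muscle markers were at 5.37 and 10.6 CPM (0.98) and Schwann cell markers at 6.17 and 12.5 CPM (1.02). Fibroblast markers, of which Dcn gave most UMIs, were at 190.9 and 242.5 CPM (0.35). T and NK markers differed by -0.02, B cell markers by -0.04 and adipocyte markers by 0.13, and all 3 intervals included 0. Among epithelial markers the basal list was at 25645 and 17417 CPM (-0.56), the luminal progenitor and alveolar list at 2415 and 2646 CPM (0.13), and the hormone-sensing luminal list at 609 and 347.7 CPM (-0.81). Few genes carried the 2 luminal sums. Lcn2 gave 64344 of 83727 and 239493 of 271689 UMIs of the former, and Krt8, Krt18 and Krt19 gave most UMIs of the latter.

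Different clusters of basal-like cells made up the 2 libraries. Clusters led by Ptx3 or Hspa1b came almost wholly from the library labelled WT. Clusters led by 1600014C10Rik, Adamts1, Gm8797 or Srxn1 came almost wholly from the library labelled Fgd5-ko. When the class was clustered on its own it gave 13 clusters, and 93.5% of its 12218 cells lay in clusters that were at least 90% of 1 library. With each gene centred within its library this was 88.1%. With 1 library per group such a cluster may be the library and not a cell state, so shares of clusters were not compared.

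Gene by gene, basal-like cells of the 2 libraries differed in both directions. The sums were 34664616 and 102691553 UMIs. Among 2378 genes with a mean of at least 50 CPM the median log2 ratio was 0.11, with 10th and 90th percentiles of -0.51 and 0.80. The 12 genes with the highest ratio included 1600014C10Rik, from 6.95 to 561 CPM (6.33, 6.15 to 6.52), and Serpina3n, a secreted acute-phase protease inhibitor, from 1.96 to 124 CPM (5.98, 5.63 to 6.34). They also included 4 replication-dependent histone genes, Hist1h3c (5.90), Hist1h1b (5.44), Hist1h1e (3.46) and Hist1h2ae (2.27). The nuclear long noncoding RNA Neat1 (2.76), Gm21190 (2.42), the mitochondrial leucyl-tRNA synthetase gene Lars2 (2.32), Ralgds (2.11), the MHC class I gene H2-Q4 (2.09) and the G protein regulator Rgs2 (2.05) completed them. The histone genes, H2-Q4 and Gm21190 have close copies, and their counts are uncertain. Hist1h2ae turned to -0.76 among cells of 4000 to 12000 UMIs. Most of the high genes were raised in cells that are not epithelial too. In fibroblast-like and endothelial-like cells Neat1 had log2 ratios of 1.62 and 2.003, Hist1h1e of 2.61 and 2.21, and Lars2 of 3.25 and 3.49. Rgs2 was at 2.915 and 0.957, Ralgds at 0.71 and 1.025 and H2-Q4 at 0.71 and 0.62. Hist1h2ae was not raised there (0.01 and -1.48), and 1600014C10Rik was less so in endothelial-like cells (4.30 and 0.28). Composition may bear on these ratios too.

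The 12 genes with the lowest ratio were led by Gm26532, from 131 to 17.2 CPM (-2.92, -3.00 to -2.84), and Gstp1, a glutathione transferase, from 109.6 to 15.8 CPM (-2.79, -2.88 to -2.71). Polr2l, a small subunit shared by RNA polymerases, was at 203 and 31.2 CPM (-2.70). Glycam1, a secreted mucin of milk and of high endothelial venules, was at 131 and 20.7 CPM (-2.66). In endothelial-like barcodes it stood at 89406 and 55835 CPM. At its ratio to endothelial markers there, the endothelial marker UMIs of basal-like cells correspond to 187 and 65.8 CPM of Glycam1, more than was measured. The others were 1700023F06Rik (-2.57), Gt(ROSA)26Sor (-2.37), Gm15867 (-2.23), the inducible heat shock gene Hspa1b (-2.02), Smim27 (-1.99), the actin-binding peptide gene Tmsb10 (-1.96), and 2 genes of the mitochondrial respiratory apparatus, Usmg5 (-1.73) and Ndufa3 (-1.68). Gstp1 has a close paralog, Hspa1b is nearly identical to Hspa1a, and Gm15867 and Gt(ROSA)26Sor are annotated as antisense, so these counts are uncertain too. Some of the low genes were about as low in cells that are not epithelial, and others were less low there. In fibroblast-like and endothelial-like cells Polr2l had log2 ratios of -2.83 and -2.65, Gstp1 of -2.90 and -2.82, Tmsb10 of -1.93 and -2.16, and Usmg5 of -1.98 and -2.05. In the same classes Gm26532 was at -1.07 and -1.44, Hspa1b at -0.69 and -0.83, Glycam1 at -2.14 and -0.68 and Gt(ROSA)26Sor at -1.69 and -0.39. These ratios may reflect composition too, since clusters within the classes were unlike between the libraries. Fibroblast-like clusters of 385 and 4 and of 0 and 211 barcodes are examples. Other scalings of the sums lowered all log2 ratios by 0.18 (TMM) or 0.19 (median ratio). Among cells of 4000 to 12000 UMIs the rule gave 6 of the same 12 highest and 8 of the same 12 lowest genes, and 11 of the 12 highest stayed above 0. The genes depend more on the minimum mean CPM: at 20 CPM the overlaps were 5 and 7, and at 200 CPM 3 and 2.

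**Figure D1:**
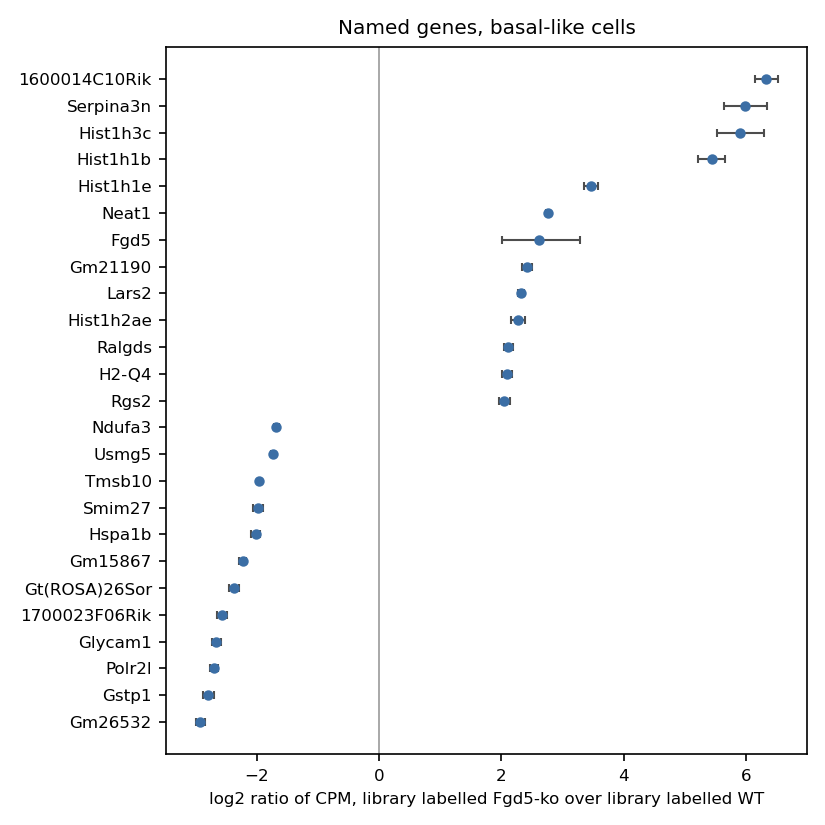
Log2 ratio of CPM (x axis, library labelled Fgd5-ko over library labelled WT) of Fgd5 and the 24 genes chosen by the rule on size, in basal-like cells. Points are ratios of summed UMIs from 1 library each and bars are exact 95% counting intervals, from 6.33 for 1600014C10Rik to -2.92 for Gm26532.

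Cell-cycle genes were higher in basal-like cells of the library labelled Fgd5-ko. All 20 genes of the G2/M list were at least 1.5-fold higher, with a median log2 ratio of 2.68, which was 2.42 above the median of random lists matched on expression (percentile 100). Mki67, an antigen of cycling cells, was at 8.11 and 74.6 CPM (3.20, 3.03 to 3.38), and Top2a, the topoisomerase of dividing cells, was at 11.6 and 83.8 CPM (2.86, 2.71 to 3.01). The kinesin Cenpe had a log2 ratio of 2.90 and the spindle gene Hmmr of 2.86. Of 20 S phase genes 17 were at least 1.5-fold higher and 3 were within 1.5-fold, with a median of 1.40, or 1.14 above matched lists (percentile 100). Mcm4 and Mcm7, subunits of the replicative helicase, had log2 ratios of 1.52 and 0.37, the ribonucleotide reductase gene Rrm1 of 1.34 and the thymidylate synthase gene Tyms of 1.22. Among cells of 4000 to 12000 UMIs Tyms (-0.33) and Mcm7 (-0.18) turned.

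At 2000 UMIs per cell, 102 of 6173 basal-like cells (1.65%, 1.35 to 2.002) in the library labelled WT and 588 of 5984 (9.83%, 9.08 to 10.6) in the library labelled Fgd5-ko had an Mki67 or Top2a UMI. Unthinned, the shares were 3.46% and 23.7%. The background in fibroblast-like cells, thinned alike, was 0.688% (0.277 to 1.41) and 1.42% (0.614 to 2.78). Cycling cells were not spread evenly over depth. With cells ordered by UMIs into 4 equal groups, from the lowest to the highest the share was 1.36%, 0.648%, 1.17% and 3.43% in the library labelled WT, and 2.61%, 4.01%, 8.16% and 24.5% in the library labelled Fgd5-ko. Among cells of 4000 to 12000 UMIs in either library (4355 and 1558 cells) the G2/M median was 0.14, inside the middle 95% of matched lists (excess -0.12, percentile 24.2), and the S phase median was -0.06, also inside (excess -0.28, percentile 3.56). In those cells the share with an Mki67 or Top2a UMI was 1.35% (1.03 to 1.74) and 2.503% (1.79 to 3.41). Among cells between the 25th and 75th percentiles of UMIs of their own library the G2/M excess was 3.89. With cycling clusters left out it was 0.40 (percentile 98.5), and the S phase excess was 0.16, inside the middle 95%. Those clusters were chosen by their cell-cycle genes, so a fall of these lists was fixed in advance. It left 6152 and 5233 cells.

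**Figure D2:**
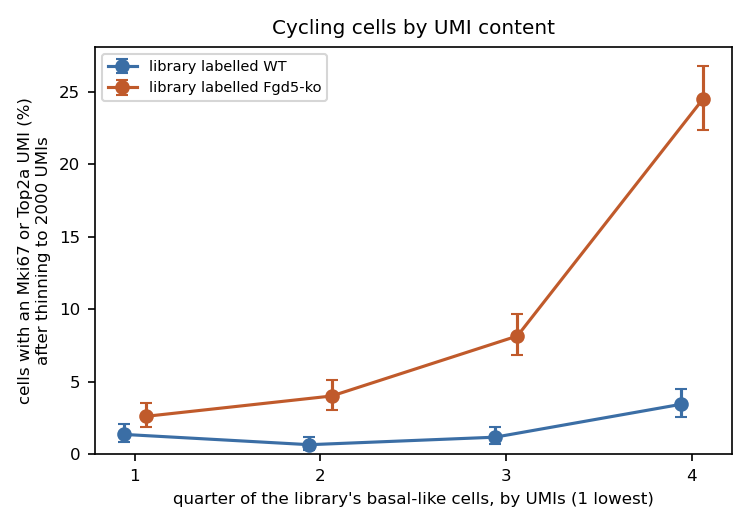
Percent of basal-like cells with an Mki67 or Top2a UMI after thinning to 2000 UMIs (y axis), in 4 equal groups of each library's cells ordered by UMIs before thinning (x axis). Points are shares of 1 library, bars exact 95% intervals; the highest group stands at 3.43% in the library labelled WT and 24.5% in the library labelled Fgd5-ko.

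Genes of antigen presentation and inflammation were higher in the library labelled Fgd5-ko. Of 13 antigen presentation genes 12 were at least 1.5-fold higher, with a median of 1.57, or 1.39 above matched lists (percentile 100). The excess was 0.73 among cells of 4000 to 12000 UMIs and 0.46 over all listed cells of any class. The MHC class II invariant chain Cd74 (15.3 and 71.5 CPM, 2.23), the immunoproteasome subunit Psmb9 (2.11), the MHC class I light chain B2m (1.85) and the peptide transporter Tap1 (1.70) were the examples. Of 15 measured NF-kB and inflammation genes 12 were at least 1.5-fold higher (median 0.79, 0.61 above matched lists, percentile 99.8), among them the apoptosis inhibitor Birc3 (1.93), the neutrophil chemokine Cxcl1 (94.3 and 294 CPM, 1.64), Relb (0.79) and Nfkbiz (0.78). Of 16 interferon response genes 9 were higher and 1 lower by at least 1.5-fold (median 0.77, 0.53 above, percentile 99.9), with Irf9 at 1.01, Ifi27 at 0.49, Isg15 at 0.39 and Ifitm3 at -0.42. Immediate early genes, which are also induced by tissue dissociation, had 11 of 18 members higher (median 0.71, 0.73 above, percentile 100), among them Btg2 (2.04), Zfp36 (1.97), Ier2 (1.87) and Egr1 (1.35). The immediate early list lay above its matched lists in fibroblast-like (1.18) and endothelial-like cells (0.76) as well, and so did the NF-kB list (0.73 and 0.63). The antigen presentation list was at 0.37 and 0.14 in those cells and the interferon list at 0.06 and -0.23.

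The luminal identity list had a lower median in basal-like cells of the library labelled Fgd5-ko. Of its 18 genes 6 were lower and 3 higher by at least 1.5-fold and 9 within 1.5-fold, with a median of -0.44, or 0.64 below matched lists (excess -0.64, percentile 0). The excess was -0.59 among cells of 4000 to 12000 UMIs and -1.85 over all listed cells, which include the luminal-like ones. Krt18, a keratin of simple epithelia, was at 215 and 67.5 CPM (-1.67, -1.72 to -1.62), Krt19 at -0.91 and Krt8 at -0.45, while the luminal transcription factor Gata3 was at 0.32. At 2000 UMIs per cell, 25.3% (24.2 to 26.4) of basal-like cells in the library labelled WT and 12.05% (11.2 to 12.9) in the library labelled Fgd5-ko had at least 2 UMIs of Krt8 and Krt18 beside at least 2 of Krt5 and Krt14. Without thinning the order was the opposite, 60.0% and 80.8%, at median depths of 4923.5 and 15725 UMIs. The share with at least 2 Krt8 and Krt18 UMIs alone was 25.97% and 13.1% in basal-like cells and 1.08% and 0.532% in fibroblast-like cells. The luminal list was also below matched lists in fibroblast-like (-0.62, 11 genes measured) and endothelial-like cells (-1.003, 6 genes measured), with Krt18 at -1.17 and -1.27. Doublets were left in, and cells of the 2 luminal-like classes were themselves fewer in the library labelled Fgd5-ko, at 17 and 5 against 118 and 53.

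The basal stem-cell, Notch, mesenchymal, Hippo and basement membrane lists lay less far below matched lists than the luminal list. The basal stem-cell associated list was 0.38 below matched lists (excess -0.38, percentile 0.79), with 9 of 12 genes within 1.5-fold; Tspan8 was at -0.77, Lgr5 at -0.36, Sox9 at 0.34 and Dll1 at 0.28. Among cells of 4000 to 12000 UMIs that list turned to 0.024 above matched lists, with Tspan8 at 0.995 and Lgr5 at 0.62. The Notch list (-0.44, percentile 1.74) had 3 of 11 genes lower and 2 higher by at least 1.5-fold, with Jag1 at -0.71, Hes1 at -0.53, Dll1 at 0.28 and Jag2 at -0.08. The mesenchymal list (-0.35, percentile 1.48) had 11 of 16 within 1.5-fold, with Tgfb1i1 at -0.47, Vim at -0.31, Snai2 at 0.29 and Sparc at -0.18. The Hippo list of YAP targets (-0.30, percentile 2.41) had 11 of 14 within 1.5-fold, with Ajuba at 0.51, Cyr61 at -0.50, Amotl2 at -0.47 and Ctgf at 0.34. The basement membrane list (-0.27, percentile 1.41) had 4 of 20 lower and 3 higher; the laminin chain genes Lama1 (1.17) and Lama3 (0.81) stood against Lama5 (-1.03), and Col17a1 was at -0.74. Each of these 5 lists entered the middle 95% of matched lists under some other setting. The Notch list did so only with the stricter cell filter (-0.39, percentile 3.07). It was further out with cells thinned (-0.58) and among cells of 4000 to 12000 UMIs (-0.61). In that range the basement membrane list was further out too (-0.40, percentile 0.19). With cells filtered more strictly the Notch, Hippo and basement membrane lists came inside. With cells thinned the mesenchymal, basal stem-cell, Hippo and basement membrane lists did. Thinning gives cells equal weight, and with equal weight of unthinned cells these lists stayed outside (percentiles 1.80, 1.46, 2.28 and 1.46). The thinned values are from 1 draw of fewer UMIs, so they show no dependence on weighting. Under either other scaling the Hippo list came inside by an edge (percentiles 2.52 and 2.53). A scaling shifts every gene alike and can change only the matching of random lists, so this is no sign of dependence on scaling. Matched on transcript length too, all 5 lists lay outside the range and further out than in the main setting. The excess was -0.48 (basal stem-cell), -0.52 (Notch), -0.39 (mesenchymal), -0.37 (Hippo) and -0.495 (basement membrane), at percentiles from 0.01 to 0.64.

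Contractile and basal identity genes, at -0.18 against matched lists (percentile 9.13), lay inside the middle 95%, with Tagln at 7178 and 3172 CPM (-1.18), Tpm2 at -0.85, Lmod1 at 0.84 and Myl9 at -0.63. It left that range (-0.33) when the random lists were matched on transcript length too. Glycolysis and hypoxia (-0.26, percentile 2.54; Hk2 -1.16, Eno1 -0.79, Hk1 0.72) lay inside at the edge and went outside under 8 other settings, among them cells thinned (-0.27), equal weight of cells (-0.28) and cells of 4000 to 12000 UMIs (-0.46). With Scrublet calls removed or lists matched on length the excess itself did not grow (-0.259 in each, against -0.261). Also inside were Wnt pathway genes (0.10, percentile 77.9) and the FGD family with CDC42 signalling (0.10, percentile 76.1; Pak1 0.95, Iqgap1 0.54). Within the Wnt list the cyclin gene Ccnd1 was at 9.89 and 68.6 CPM (2.79) and the ligand gene Wnt10a at 1.56, while the secreted inhibitor gene Sfrp1 was at -1.35, and at 0.12 among cells of 4000 to 12000 UMIs. Milk and alveolar genes (-0.03, percentile 45.7; Glycam1 -2.66, Lcn2 0.33), heat shock (-0.04, percentile 40.1; Hspa1a -1.14, Hsp90aa1 0.85), the unfolded protein response (-0.15, percentile 15.6; Ddit3 1.83, Pdia4 -1.19), p53 targets (0.04, percentile 59.0; Fas 0.49, Gadd45a -0.36) and cholesterol synthesis (0.08, percentile 71.8; Cyp51 1.29, Fdps -0.34) also lay inside.

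**Figure D3:**
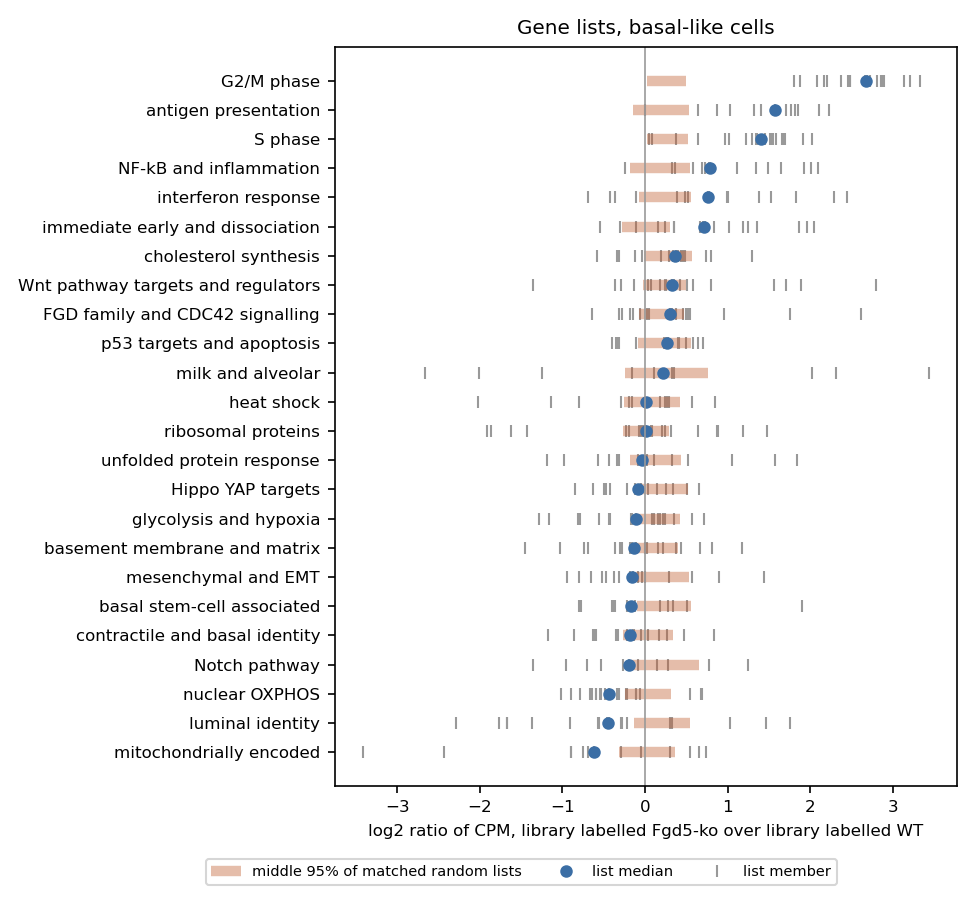
Log2 ratio of CPM (x axis, library labelled Fgd5-ko over library labelled WT) for 24 gene lists in basal-like cells, 1 library each. Dots are list medians, ticks members, and shaded bars the middle 95% of 10000 random lists matched on expression; the G2/M median of 2.68 lies farthest right and the mitochondrially encoded median of -0.62 farthest left.

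The 2 lists of mitochondrial respiration had lower medians in the library labelled Fgd5-ko, with members that went both ways. Of 13 mitochondrially encoded genes 7 were lower and 2 higher by at least 1.5-fold (median -0.62, excess -0.61, percentile 0.03). The members mt-Nd4l (2652 and 249 CPM, -3.41) and mt-Atp8 (-2.43) were below mt-Nd3 (-0.89) and mt-Co1 (-0.89). Of 21 nuclear genes of oxidative phosphorylation 7 were lower and 2 higher (median -0.44, excess -0.43, percentile 0.08), with Atp5e at -1.02, Cox7c at -0.89, Ndufa1 at -0.79 and Cox4i1 at 0.69. The nuclear list lay below matched lists in fibroblast-like (excess -0.57) and endothelial-like cells (-0.60) too, and the mitochondrially encoded list in endothelial-like cells (-0.82), while it was at -0.25 in fibroblast-like cells (percentile 11.03). The ribosomal protein list had a median of 0.01 (excess 0.03, percentile 62.7) over members that went both ways, from Rpl38 (-1.91), Rps29 (-1.87) and Rps27 (-1.62) to Rpl5 (1.47). Among 2474 genes with a mean of at least 50 CPM and a known length, longer transcripts had higher median ratios. Genes whose median transcript is under 700 nt had a median log2 ratio of -0.20 (311 genes) and those of 1500 nt and more 0.26 (1421 genes), a difference of -0.46. The difference was -0.33 in fibroblast-like and -0.57 in endothelial-like cells of the same libraries. Matched on transcript length too, the excess of the nuclear list was smaller in size, at -0.30 (percentile 0.475). That of the mitochondrially encoded list was -0.54 (percentile 0.06).

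**Figure D4:**
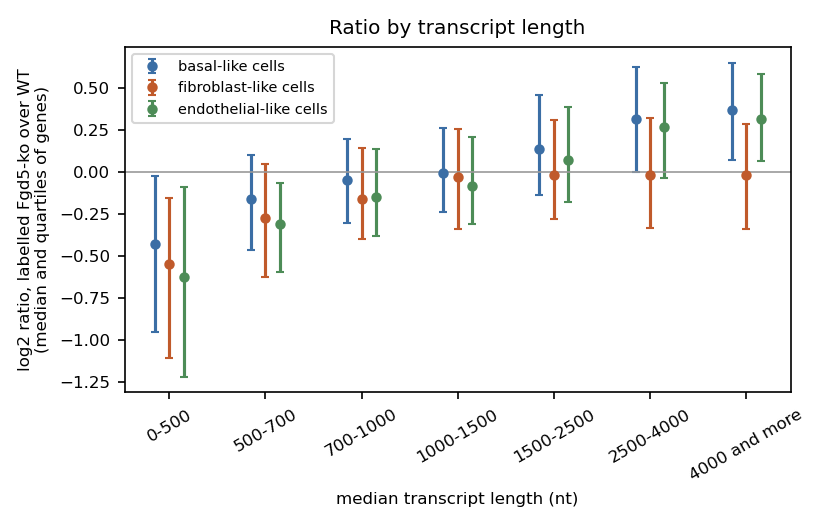
Log2 ratio of CPM (y axis, library labelled Fgd5-ko over library labelled WT) by median annotated transcript length in nt (x axis), for basal-like, fibroblast-like and endothelial-like cells, 1 library each. Points are medians over genes and bars their quartiles; below 500 nt the medians are -0.42, -0.55 and -0.62.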

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

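Of the tests in this part, 4 were set before the result they measure was seen: detection of cycling cells, transcript length in other cell types, short genes without ribosomal and mitochondrial ones, and length-matched lists. Those on length were added after other results were seen, but before their own. The tests of endothelial RNA, depth for Fgd5, exchanged labels, tags outside the deleted part, length within ribosomal protein genes, larger cells, the UMI limit and other cell types' cycling were chosen after.

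Barcodes outside the authors' table held other cell types, a signal in data outside the comparison. Endothelial-like barcodes were 36.6% (1276) of those passing the filter in the library labelled WT and 16.8% (273) in the library labelled Fgd5-ko. Fibroblast-like barcodes were 30.2% (1054) and 35.2% (572). In endothelial-like barcodes Fgd5 stood at 100.4 CPM (92.0 to 109.5) and 125.6 CPM (112 to 140.6), far above its level in basal-like cells. In fibroblast-like barcodes Procr stood at 130 CPM (122 to 139) and 239.5 CPM (229 to 251).

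Fgd5 was higher in basal-like cells of the library labelled Fgd5-ko (log2 ratio 2.61). The endothelial marker UMIs in those cells argue against RNA of endothelial cells, as they would bring 0.148 CPM of Fgd5, against 4.05 CPM measured. A tie to deeper cells cannot be told apart from a difference between the libraries: the ratio fell to 1.26 (0.36 to 2.18) among cells of 4000 to 12000 UMIs, on 20 and 26 UMIs, while it was 3.40 (2.25 to 4.86) between the 25th and 75th percentiles of each library. The ratio with cells thinned, set before as the test of depth, decides nothing, since CPM are already divided by the totals and thinning leaves the expected share of a gene's UMIs in each cell as it was. Exchanged labels cannot be told apart from a true difference, since Fgd5 in the library labelled WT was only 0.664 CPM and no second library of either genotype was there to compare. Tags from outside the deleted part cannot be told apart either: Fgd5 UMIs remained in endothelial-like cells of the library labelled Fgd5-ko at a log2 ratio of 0.32 (0.11 to 0.53), and while the word cko in the title marks a conditional knockout by usual use, which would leave Fgd5 in other cell types, neither the deleted part nor the cell types are given.

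Short transcripts were lower in the library labelled Fgd5-ko. The shortfall of genes under 700 nt against those of 1500 nt and more was present in fibroblast-like (-0.33), endothelial-like (-0.57) and basal-like cells (-0.46). A loss of short molecules in library preparation would give such a shortfall in every cell type. By the longest transcript the differences were -0.57, -0.79 and -0.60. The trend among long transcripts was not alike, however. Between genes of 1500 to 2500 nt and those of 4000 nt and more the median rose from 0.14 to 0.37 in basal-like and from 0.07 to 0.32 in endothelial-like cells. In fibroblast-like cells it was -0.02 in both. A loss of short molecules alone would not give a rise among long transcripts in some cell types only, so it is not shown to be the whole cause. A change of ribosomal and mitochondrial genes alone is argued against by the same difference without those genes, -0.43. Whether those genes changed besides in basal-like cells stays open, because within ribosomal protein genes the short ones lay 0.34 below the long ones (-0.34), between the bounds set.

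Cell-cycle genes were higher in the library labelled Fgd5-ko. For the shares of cells with an Mki67 or Top2a UMI, detection at unequal depth as the whole cause is argued against by the shares at 2000 UMIs per cell, whose ratio was 5.95. For the summed genes, the authors' upper UMI limit as the whole cause is argued against by the G2/M median with unlisted basal-like cells added. It was 2.11, down from 2.68 in the listed cells, on adding 211 and 368 cells. The choice of cells thus bears on its size. Loss of short molecules is argued against by the G2/M list's percentile of 100 among lists matched on length. A tie to larger or deeper cells cannot be told apart from more cycling: among cells of 4000 to 12000 UMIs the G2/M excess was -0.12, while it was 3.89 between the 25th and 75th percentiles of each library, and the first range takes the shallowest cells of the deeper library. A difference across all cell types cannot be told apart either, since the G2/M excess was 2.62 in endothelial-like cells (9 genes measured) and 0.54 in fibroblast-like cells (13 genes), and the genotype itself stays untested.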

How the results depend on the processing

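The alternatives added after the data were seen are the 2 UMI ranges, cycling clusters left out, unlisted cells added, length-matched lists, centring for the clusters of basal-like cells, the longest transcript and the Procr thinning depths. Each group has 1 library, so depth limits low genes such as Fgd5 and no alternative measures the spread between animals. No paired analysis was possible because each group has 1 library. The filter of at least 200 genes was not run, since cells came from the authors' table. Of 390 values of the 36 main results under alternatives, 333 kept their direction and side of the matched range or stayed within their interval. These include the lists under the 2 other scalings, which shift every gene alike and so leave the excess of a list nearly as it was. They also include 34 values with Scrublet calls removed, which left 6226 and 5984 basal-like cells against 6234 and 5984 and so could change little. Of 1276 values of single genes 631 stayed within their interval, 634 moved and 11 turned. Of those that stayed, 116 are from the removal of Scrublet calls. The cause of the changes below was not tested, except where the setting itself sets the value (thinning depth, UMI minimum, resolution).

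The Fgd5 log2 ratio was 1.26 among cells of 4000 to 12000 UMIs and 3.40 between the 25th and 75th UMI percentiles of each library. With cells thinned to 2000 UMIs it was 3.69 (2.24 to 5.62) on 4 and 50 UMIs, an interval that holds the main 2.61. That value is from 1 draw, which gave the lowest Fgd5 share of the library labelled WT among 10, so it shows no effect of thinning. Among cells of 4000 to 12000 UMIs the excess turned for the G2/M (-0.12), S phase (-0.28) and basal stem-cell (0.024) lists. The same range took the mesenchymal (-0.21) and Hippo (-0.11) lists inside the middle 95% of matched lists and glycolysis outside it (-0.46). Single genes that turned there were Hist1h2ae (-0.76), Vim (0.016), Tspan8 (0.995), Lgr5 (0.62), Sfrp1 (0.12), Tyms (-0.33), Mcm7 (-0.18) and Gadd45a (0.19). Between the 25th and 75th percentiles Mfge8 (0.25) and Jag2 (0.0025) turned, and the mesenchymal (-0.30) and basement membrane (-0.077) lists came inside. With cycling clusters left out the G2/M excess fell to 0.40 but stayed outside, Mcm7 turned (-0.27) and the S phase (0.16), Hippo (-0.23) and basement membrane (-0.23) lists came inside. The fall of the cell-cycle genes there was fixed in advance by how those clusters were chosen.

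With thinned cells the mesenchymal (-0.27), basal stem-cell (-0.32), Hippo (-0.28) and basement membrane (-0.16) lists came inside. With equal weight of unthinned cells they stayed outside, and the thinned values are from 1 draw. With the stricter filter the Notch (-0.39), Hippo (-0.29) and basement membrane (-0.22) lists came inside. The Hippo list also came inside with all listed cells (-0.24), unlisted cells added (-0.28) and members of at least 100 UMIs (-0.29). With TMM (-0.29) and median-ratio (-0.29) scaling it came inside by an edge (percentiles 2.52 and 2.53), through the matching of random lists alone. The basement membrane list did with all listed cells (-0.20), unlisted cells added (-0.24) and at least 100 UMIs (-0.24). Glycolysis and hypoxia, on the edge at first, went outside with equal weight of cells (-0.28), thinned cells (-0.27), the stricter filter (-0.26), Scrublet calls removed (-0.26), all listed cells (-0.28), cycling clusters left out (-0.28) and length-matched lists (-0.26). Where the excess stayed at -0.26 the crossing may come from the draw of random lists and shows no stronger shift. Length matching also took the contractile list outside (-0.33). It moved the Notch (-0.52), basement membrane (-0.495), basal stem-cell (-0.48), mesenchymal (-0.39) and Hippo (-0.37) lists further out. The nuclear oxidative phosphorylation list came nearer to its matched lists (-0.30) but stayed outside.

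The basal-like share was 95.3% in the library labelled WT with the stricter filter and 91.7% in the library labelled Fgd5-ko at Leiden resolution 2. At 1000 UMIs per cell the luminal keratin shares were 9.74% and 3.71%, the Mki67 or Top2a shares 1.06% and 7.05%, and the Procr share of the library labelled Fgd5-ko 0.334%. At 4000 UMIs they were 50.7% and 30.1%, 3.01% and 13.2%, and 0.461% and 1.61%. With at least 1 or 3 luminal keratin UMIs the shares were 56.7% and 40.8%, or 10.8% and 3.63%. With at least 2 Mki67 or Top2a UMIs they were 0.470% and 5.06%. In each pair the order of the libraries was that of the main value. Basal-like cells gave 8 clusters at resolution 0.3.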

Other observations

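Both tests in this part bear on 1 gene; the test of its level in other cell types was set before its result was seen, and the same values were used for transcript length after.

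Endothelial-like barcodes outside the authors' table held a group led by Glycam1, Ptgds, Ubd, Ccl21a, Serpina1e, Pglyrp1, Fut7, Oit1, Ly6i and Chst4. Some of these, such as Glycam1, Fut7 and Chst4, are known from the high endothelial venules of lymph nodes. In the endothelial-like class Glycam1 stood at 89406 CPM in the library labelled WT and 55835 CPM in the library labelled Fgd5-ko (log2 ratio -0.68). That group held 163 of 1276 endothelial-like barcodes in the library labelled WT and 20 of 273 in the library labelled Fgd5-ko, so its unequal share bears on this ratio. In basal-like cells Glycam1 was at 131 and 20.7 CPM. Other endothelial groups had Gkn3, Stmn2 and Sema3g, genes of arteries, or Sele, Vwf, Selp and Ackr1, genes of veins, among their leading genes. These vessel types were read from the leading genes after they were seen and were not tested with a fixed list.

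Gm42418 and Lars2 were higher in the library labelled Fgd5-ko in all 3 cell classes. Gm42418, which overlaps a ribosomal RNA repeat, was at 6761 and 21286 CPM in basal-like cells (log2 ratio 1.65), at 5406 and 41220 CPM in fibroblast-like cells (2.93) and at 6710 and 42404 CPM in endothelial-like cells (2.66). Lars2 had log2 ratios of 2.32, 3.25 and 3.49 in the same classes. The genes 1600014C10Rik (6.33, 4.30 and 0.28) and Serpina3n (5.98, 2.20 and 4.03) were not alike across them. These genes were picked after their values were seen.

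Gt(ROSA)26Sor, the noncoding transcript of the Rosa26 locus where transgenes are often placed, was lower in basal-like cells of the library labelled Fgd5-ko (-2.37). A Rosa26 allele altered alike in every cell is a hypothesis that its log2 ratio in endothelial-like cells argues against, since it was -0.39 (-0.74 to -0.05) there and -1.69 in fibroblast-like cells. Loss of short molecules in library preparation, which would act alike in every cell type, is argued against as the whole cause by the same values, as the ratio in basal-like cells lay 1.98 below that in endothelial-like cells (difference -1.98). Clusters within the endothelial-like and fibroblast-like classes were unlike between the libraries, so composition may bear on both arguments. An allele altered in some cell types only, as a conditional design (cko in the title) allows, stays open. So does its overlap with genes on the other strand, and any difference of basal-like cells themselves.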
